A study of Mus musculus with 5 samples.

How the data were processed

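The series comprised 5 single-cell RNA sequencing libraries of mouse liver, 1 per group: a whole liver after 8 CCl4 injections, and sorted stellate cells from an untreated liver and after 1, 4 and 12 injections. Per the labels' protocols, libraries were made with the Chromium Single Cell 3′ kit of 10x Genomics and sequenced on Illumina instruments, and the sorted cells were purified by gradient centrifugation and sorting for LratCre-induced TdTom. Per the submitters' processing notes, reads were processed with Cell Ranger 2.0.0 against mm10. The authors deposited filtered gene by barcode matrices of UMI counts, 1 per library, which are whole numbers and not normalised. Settings of the barcode filter, the annotation release and the number of animals behind each library are not given in the sources used here. The labels' treatment text also names feeding models, which were not analysed here.

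All further values were computed from the deposited counts. The files list 28692 genes, of which 28339 identifiers were matched to GENCODE vM21 for coordinates on mm10, and 58 symbols are used more than once. Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs. In the whole liver 242 barcodes were under the gene minimum and 347 over the mitochondrial limit, with 2 over the limit in the library with 12 injections and none elsewhere. Doublets were scored with Scrublet in scanpy, and the highest-scoring barcodes were removed at 0.8% per 1000 barcodes of the library. This took out 55 barcodes from the whole liver, 74 from the untreated library, and 99, 62 and 82 from the libraries with 1, 4 and 12 injections, leaving 2202, 2962, 3411, 2716 and 3117 cells. The automatic Scrublet threshold marked only 7, 0, 3, 4 and 3 barcodes and was used as an alternative.

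Each library was analysed on its own: normalisation to 10000 UMIs per cell, log transformation, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1. This gave 25 clusters in the whole liver and 13, 13, 13 and 14 in the sorted libraries. Clusters were named from the markers of 19 cell classes fixed before the data were examined. The naming thresholds were set after the data were seen: a class score of at least 0.35, at least 3 markers at 0.5 of their range over clusters or more, and a second class below 0.8 of the best score. A cluster whose 10 leading genes held more markers of another class stayed unnamed. Names read "like" because they come from markers and not from an annotation of cells, and shares of classes may differ from those of an annotation made in another way.

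For each library the UMIs of HSC-like cells were summed and scaled to that sum as CPM, computed here from the deposited counts. Exact Poisson intervals for CPM, exact Clopper-Pearson intervals for shares of cells, and exact binomial intervals for ratios of 2 counts are at the 95% level and cover counting error only. A count of 0 is given with the limit that 3 counts allow. To compare shares of cells across depths, every cell was thinned once at random to 1000 and to 2000 UMIs. The depth of the HSC-like sums was 17353134 UMIs without treatment, and 28118434, 25665506 and 23090510 after 1, 4 and 12 injections. At that depth 3 counts are worth 0.173, 0.107, 0.117 and 0.130 CPM.

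Genes were compared when they had at least 50 CPM in either library, by the log2 ratio with 10 CPM added to both, and counted when the ratio was at least 2 in either direction. With 1 library per group no pair of groups could be tested across samples, and each count is a count past a size rule. A linear trend of log2 CPM (10 CPM added) over the number of injections was fitted by least squares to the 4 sorted libraries for 3253 genes with at least 50 CPM in any of them, with Benjamini-Hochberg adjustment, and for P2ry14 an exact permutation test over all 24 orders of the libraries was used. Overlaps of such counts are given beside the number independent lists would share and beside 100 simulations of unchanged libraries against the same untreated library. The 22 gene lists were fixed before the data were examined. A list's median was set against 10000 random lists of the same size drawn within 20 bins of mean expression, using members with at least 10 CPM in at least 1 sorted library.

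The genes named were chosen by a rule written before the data were examined. It takes P2ry14, and per comparison the 12 highest and 12 lowest log2 ratios among compared genes, leaving out mitochondrial, ribosomal protein, hemoglobin, Xist and Y-linked genes, unnamed gene models and the markers of classes other than HSC. It also takes the 2 highest and 2 lowest members of each list, the purinergic receptors with UMIs in at least 5% of the cells of a class, and the 12 genes with the highest ratio of HSC-like to other cells in the whole liver. Of the list members that the rule takes, the text prints a part, chosen after their values were seen. One further gene that the rule names is not reported here. Genes named outside the rule were chosen after their values were seen: Lrat and Col1a1 as a description of clusters, Acta2, Top2a, Cd74 and Reln where the untreated cluster or a list is described, the other measured members of the purinergic list, and the genes of the closing section.

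The comparison was tested on simulated data drawn from the means of the untreated library, at the depth of each library, with 200 genes altered by a known factor. Genes altered 2.5-fold and 4-fold were recovered at 100% in each direction and each of the 3 comparisons with untreated, among 2765 to 2818 genes tested, and genes altered 1.5-fold, below the size rule, were recovered at 0%. No unaltered gene was called (0). The simulated counts hold counting error only, and the altered genes lay well above the minimum of 50 CPM. These outcomes therefore say nothing of differences between animals. A list shifted 1.5-fold came out at percentile 100, and of 21 other lists 0 lay outside the middle 95%.

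Alternatives tried, 17 in all, were a mitochondrial limit of 10% or none, no doublet removal or the automatic threshold, Leiden resolutions of 0.5 and 2, thinning to 1000 and 2000 UMIs, all kept barcodes of the sorted libraries, TMM factors from edgeR, a mean over cells in place of the sum, 1 CPM in place of 10 added, minimum CPM of 20, 200 or none, and a pair added after the data were seen: leaving out the activated cluster of the untreated library, and adding the unnamed clusters that scored highest as HSC. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16. Free RNA was not removed from the counts, and splicing, genotype and the reporter transcript were not analysed here.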

Results

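Droplet single-cell RNA sequencing (10x Genomics Chromium, 3′ end) was used to measure gene expression in the livers of C57BL/6J mice injured with carbon tetrachloride (CCl4), a toxin that kills hepatocytes and leads to fibrosis when given repeatedly. The series comprised 5 libraries with 1 library per group. One library held cells of a whole liver after 8 CCl4 injections, perfused, digested and enriched for non-parenchymal cells. The other 4 libraries held hepatic stellate cells (HSC) from an untreated liver and from livers after 1, 4 and 12 injections, purified by gradient centrifugation and sorted for the TdTom reporter that LratCre switches on. The series title names the purinergic receptor P2Y14, a receptor for UDP-sugars encoded by P2ry14, as a link between hepatocyte death and stellate cell activation, so the comparisons asked which cells of the injured liver carry P2ry14 transcripts, and how P2ry14 and the rest of the transcriptome of stellate cells differed between untreated and injured liver.

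The whole liver library held 2625 barcodes with 14988105 UMIs (unique molecular identifiers, each standing for 1 counted molecule) and a median of 4161 UMIs per barcode. The sorted libraries held 3036 barcodes and 18067487 UMIs without treatment, 3510 and 32959567 after 1 injection, 2778 and 28317989 after 4 injections, and 3201 and 30069197 after 12 injections. The median UMI count per barcode was 4206 in the untreated library and 7987, 9594.5 and 8724 in the libraries with 1, 4 and 12 injections. Whether the lower count without treatment comes from sequencing depth or from less RNA per cell was not tested. With 1 library per group there is no replicate check on any difference, and no pair of groups could be tested across animals. The only test across libraries is a linear trend over the number of injections in the 4 sorted libraries, which leaves 2 residual degrees of freedom and was added after the other results were seen. Apart from those of the trend and of matched cells in the closing section, intervals are exact 95% intervals. They are Poisson for sums of UMIs, Clopper-Pearson for shares of cells and binomial for ratios of 2 counts, and they cover counting error only. Those of the matched cells are 95% normal approximations, which also cover counting error only. Every difference is a difference between 2 libraries.

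After filtering, 2202 cells of the whole injured liver remained, and their clusters were named from marker genes. Endothelial-like cells were the most frequent with 603 cells (27.4%), followed by 399 macrophage- or monocyte-like cells (18.1%), 308 hepatocyte-like cells (13.99%), 247 HSC-like cells (11.2%, 95% interval 9.93% to 12.6%), 165 T-like cells (7.49%), 127 dendritic-like cells (5.77%), 79 B-like cells (3.59%) and 71 plasmacytoid dendritic-like cells (3.22%, 2.53% to 4.05%). Plasma-like (35), NK-like (31), cholangiocyte-like (23) and mesothelial-like (21) cells made up most of the rest. A further 93 cells (4.22%) stayed unnamed, of which 33 carried markers of endothelial cells and HSC together, 44 carried markers of macrophages and HSC together, and 16 lay in a cluster whose leading genes went against its best-scoring class. The tissue was enriched for non-parenchymal cells, so these are shares of captured cells and not of the liver.

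The first question was which cells of the injured liver carry P2ry14 (ENSMUSG00000036381, a protein-coding gene on the minus strand of mm10 chromosome 3, 59113855 to 59153618). The highest level was in plasmacytoid dendritic-like cells, with 244 CPM (UMIs scaled to the total of the class; 95% interval 196 to 300.5) and a P2ry14 UMI in 46 of 71 cells (64.8%, 52.5% to 75.8%). HSC-like cells came second with 76.3 CPM (64.5 to 89.6) and a UMI in 93 of 247 cells (37.7%, 31.6% to 44.0%). The HSC-like cells were deeper, with a median of 7857 UMIs against 4703. After thinning every cell to 1000 UMIs the share was 9.31% in HSC-like and 16.9% in plasmacytoid dendritic-like cells. Dendritic-like cells reached 18.5 CPM and 11.02% of cells, and macrophage- or monocyte-like cells 17.5 CPM and 8.52%.

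Hepatocyte-like cells, with a median of 4975.5 UMIs, gave the background: 2 of 308 cells (0.649%, 0.079% to 2.33%) held a P2ry14 UMI. Endothelial-like cells, with a median of 3143 UMIs, held it in 1 of 603 cells (0.166%, 0.004% to 0.920%) and T-like cells in 0.606% of cells. P2ry14 was not detected in 79 B-like, 31 NK-like, 23 cholangiocyte-like or 21 mesothelial-like cells, which allows shares of cells with a UMI of up to 3.797%, 9.68%, 13.04% and 14.3%. Both the plasmacytoid dendritic-like and the HSC-like shares lay above the hepatocyte-like and endothelial-like shares by more than counting error.

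**Figure D1:**
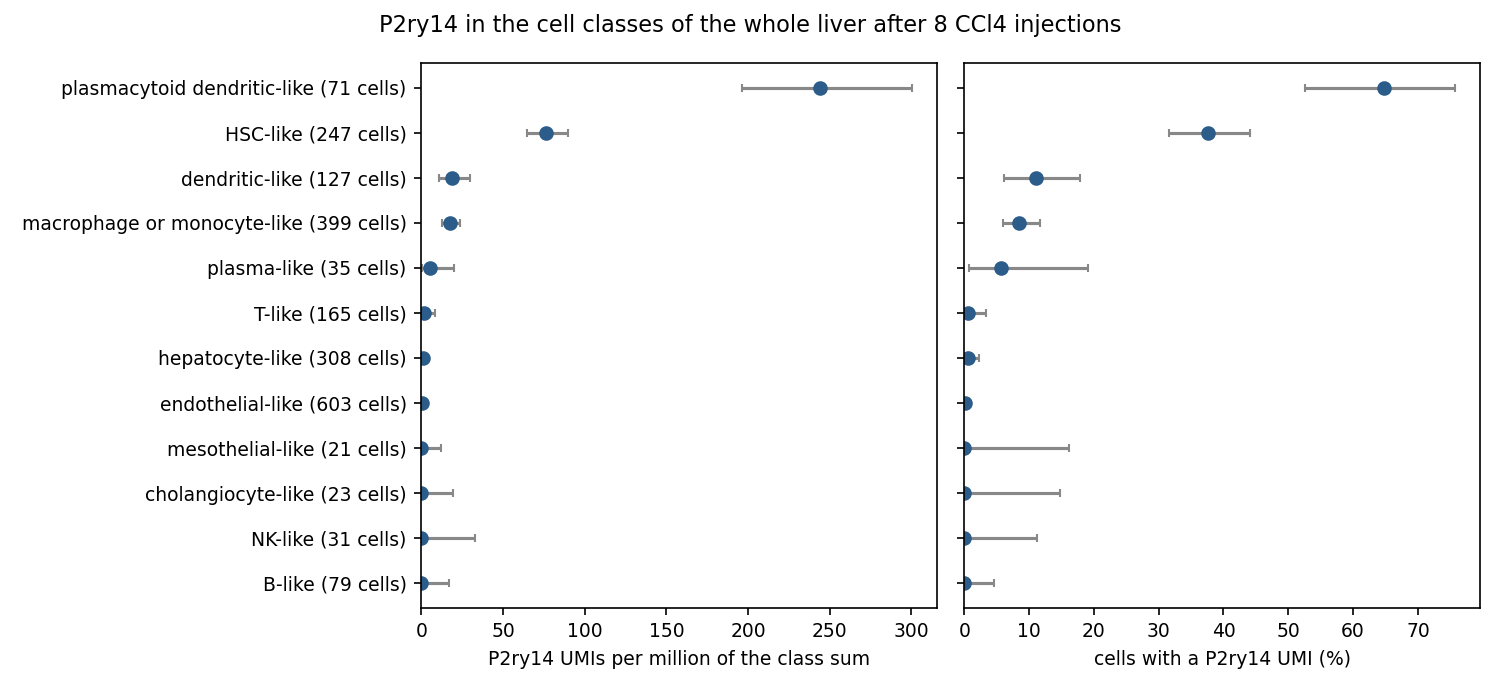
P2ry14 in each cell class of the whole injured liver, as CPM of the summed cells of the class and as the percentage of its cells with at least 1 UMI, with 95% counting intervals as bars. Plasmacytoid dendritic-like cells (244 CPM, 64.8% of cells) and HSC-like cells (76.3 CPM, 37.7%) lie above every other class.

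Among 3594 genes with at least 50 CPM in HSC-like cells or in all other cells together, P2ry14 ranked 378 by the ratio of HSC-like to other cells (76.3 against 15.8 CPM, log2 ratio 1.74 with 10 CPM added). That rank is over all of these genes. Mitochondrial, ribosomal protein and hemoglobin genes, Xist, unnamed gene models and the markers of other classes were then left out. Of the rest, the 12 genes with the highest ratio were Colec11 (1781 against 62.6 CPM, log2 4.62), Col1a1 (5662 against 229 CPM, log2 4.57), Lum (4.41), Tagln (4.35), Col1a2 (4.33), Col3a1 (4.32), Tcf21 (4.27), Sod3 (4.18), Dcn (11732 against 658 CPM, log2 4.14), Ifitm1 (4.10), Cxcl12 (4.08) and Sparcl1 (4.04). Colec11 and Dcn are among the markers that named the class. The HSC-like cells fell into a pair of clusters that differed in P2ry14. The cluster with more Lrat, the retinol-esterifying enzyme of vitamin A storing stellate cells, had 1509 CPM of Lrat, 1469 CPM of Col1a1 and 136 CPM of P2ry14 (111 to 164), and the cluster with more collagen had 525 CPM of Lrat, 8409 CPM of Col1a1 and 37.3 CPM of P2ry14 (27.1 to 50.1).

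Other purinergic receptors with UMIs in at least 5% of the cells of a class were spread differently. P2rx4 was the most widely detected, in 59.1% of macrophage- or monocyte-like, 33.3% of mesothelial-like, 26.1% of cholangiocyte-like, 25.9% of HSC-like, 19.5% of hepatocyte-like and 18.1% of endothelial-like cells. Macrophage- or monocyte-like cells also held P2ry6 (48.1%), P2ry13 (24.1%), P2ry12 (21.6%) and P2rx7 (19.0%). Dendritic-like cells held P2ry6 (35.4%) and P2ry10 (17.3%), plasmacytoid dendritic-like cells P2ry13 (19.7%), and T-like cells P2rx7 (16.4%). HSC-like cells held Adora2a in 17.4% and P2ry1 in 13.8% of cells, while endothelial-like cells held them in 9.45% and 16.4%. Adora1 (34.8%), P2ry1 (21.7%), P2ry2 (13.04%) and P2rx2 (8.70%) were detected in the 23 cholangiocyte-like cells, and Adora2b (19.0%) in the 21 mesothelial-like cells. These shares are as counted and differ in depth between classes. In HSC-like cells the share with P2ry14 was higher than that with any of the other receptors reported.

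The second question was how stellate cells differ over the course of injury. HSC-like cells made up 98.1% of the untreated library (2905 cells), 86.2% after 1 injection (2941), 93.1% after 4 (2529) and 77.4% after 12 (2414). The lower shares came mostly from clusters left unnamed by naming thresholds that were set after the data were seen. Clusters with HSC and endothelial markers together held 57 cells in the untreated library (1.92%, 1.46% to 2.49%), 400 after 1 injection (11.7%, 10.7% to 12.9%) and 12 after 4 injections (0.442%). Clusters with HSC markers and portal fibroblast or smooth muscle markers held 146 cells after 4 injections (5.38%, 4.56% to 6.29%) and 625 after 12 (20.1%, 18.7% to 21.5%). A cluster of 23 cells after 4 injections carried macrophage markers. Cells named as other classes were 70 macrophage- or monocyte-like cells after 1 injection, 6 mesothelial-like cells after 4, and 29 macrophage- or monocyte-like, 27 endothelial-like and 22 mesothelial-like cells after 12. The sort sets these shares, so they do not describe the liver. The comparisons below used the HSC-like cells alone, which held 17353134, 28118434, 25665506 and 23090510 UMIs in the libraries with 0, 1, 4 and 12 injections.

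P2ry14 was lower in HSC-like cells of every injured library than in those of the untreated library. It stood at 76.6 CPM (72.5 to 80.8; 1329 UMIs) without treatment, 52.1 CPM (49.5 to 54.8; 1465 UMIs) after 1 injection, 42.8 CPM (40.3 to 45.4; 1099 UMIs) after 4 and 36.5 CPM (34.1 to 39.1; 843 UMIs) after 12. The ratios to untreated were 0.680 (0.631 to 0.733), 0.559 (0.516 to 0.606) and 0.477 (0.437 to 0.520), or −0.56, −0.84 and −1.07 on the log2 scale. A linear trend of log2 CPM over the number of injections was not significant for P2ry14, with a slope of −0.06 per injection (95% interval −0.18 to 0.06; exact permutation test over the 24 orders of the libraries, p = 0.167). In least squares fits none of 3253 genes passed an adjusted p of 0.05 (0). P2ry14 was lower at each step, so no other order of its 4 values falls more steeply. No fall could therefore have given a lower p in the permutation test. With 4 libraries and 2 residual degrees of freedom, a gene could hardly pass adjustment over so many genes. Neither result argues against a decline. With TMM factors, which rescale the libraries to a common bulk of genes, the log2 ratios were −0.19, −0.67 and −0.89, and without an untreated cluster of activated cells described below they were −0.71, −0.99 and −1.22. The share of cells with a P2ry14 UMI as counted was 31.8%, 34.5%, 31.1% and 25.5% over the course of 0, 1, 4 and 12 injections, in libraries of unequal depth. With every cell thinned to 2000 UMIs, in 1 random draw that left out no cell, the shares were 14.7%, 10.5%, 9.09% and 6.50%.

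**Figure D2:**
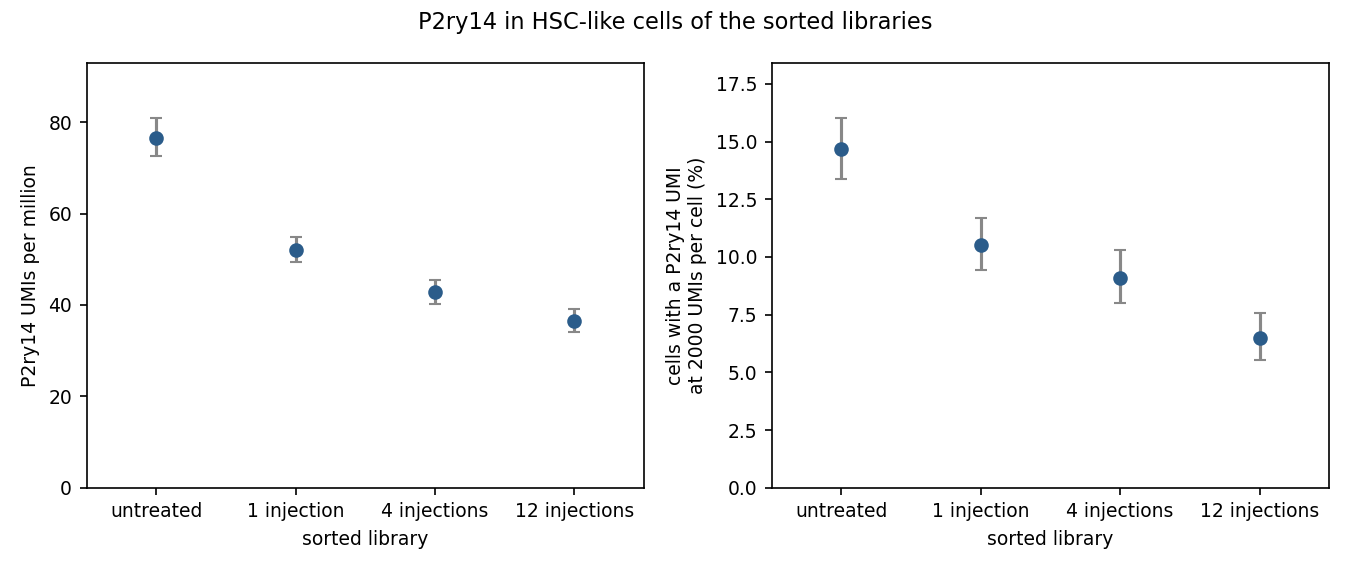
P2ry14 in HSC-like cells of the 4 sorted libraries by number of CCl4 injections, as CPM and as the percentage of cells with a UMI after thinning to 2000 UMIs, with 95% counting intervals as bars. CPM lies at 76.6, 52.1, 42.8 and 36.5, and the share at 14.7%, 10.5%, 9.09% and 6.50%.

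P2ry14 also differed between clusters within a library. In the untreated library 10 of the 12 HSC-like clusters lay between 63.5 and 114 CPM, and 2 lay lower, an activated cluster at 33.5 CPM and a cluster of 28 cells at 35.1 CPM that had 541 CPM of Top2a, a gene of dividing cells, against at most 124 CPM in any other untreated cluster. After 1 injection the clusters ranged from 29.8 to 78.3 CPM, after 4 injections from 18.2 to 86.8 CPM, and after 12 injections from 8.43 to 77.4 CPM. The cluster with the highest P2ry14 after 4 injections had 1059 CPM of Lrat and 618 CPM of Col1a1, and the one with the lowest had 315 and 8293 CPM. After 12 injections the corresponding values were 551 and 647 CPM for the highest, and 73.1 and 5381 CPM for the lowest.

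**Figure D3:**
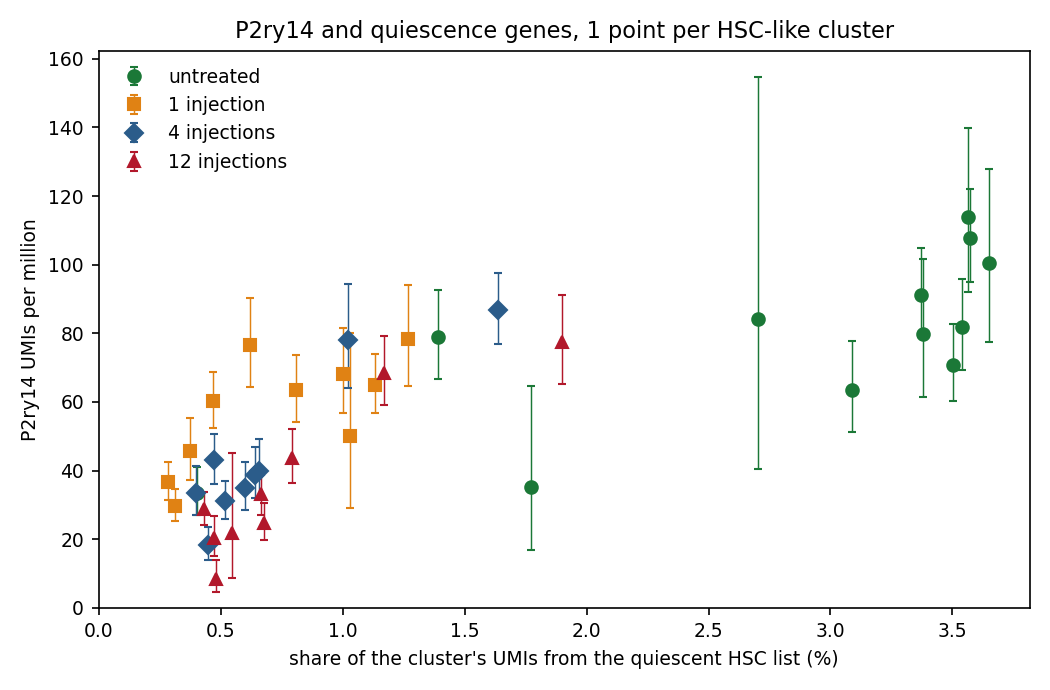
P2ry14 CPM of each HSC-like cluster against the percentage of the cluster's UMIs that come from a list of genes of quiescent stellate cells, 1 point per cluster, coloured by library. The untreated activated cluster has 0.40% of its UMIs from the list and 33.5 CPM of P2ry14, against 3.57% and 108 CPM in the largest untreated cluster.

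Transcriptome-wide differences were counted among genes with at least 50 CPM in either of the 2 libraries, after 10 CPM were added to both. The median log2 ratio of the compared genes was −0.18, −0.16 and −0.13 for 1, 4 and 12 injections against untreated, so the split between higher and lower genes depended on the scaling. After 1 injection 173 of 3070 genes were at least 2-fold higher and 470 at least 2-fold lower than in untreated cells, and 373 and 236 with TMM factors. After 4 injections 134 of 3001 were higher and 193 lower, and 154 and 138 with TMM factors. After 12 injections 112 of 2967 were higher and 181 lower, and 146 and 120 with TMM factors. The percentage of higher genes among those past 2-fold was 26.9%, 41.0% and 38.2%, and 61.2%, 52.7% and 54.9% with TMM factors.

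One untreated cluster weighed on these counts. It held 111 cells (3.75% of the library) with a median of 26287 UMIs against 4197 in the library, so that it contributed 16.1% of the untreated UMIs, and it had 2867 CPM of Acta2, the smooth muscle actin of activated stellate cells, against 132 CPM in the other untreated HSC-like cells. Without it the counts were 247 higher and 568 lower after 1 injection, 176 and 292 after 4, and 140 and 263 after 12. In comparisons of the injured libraries with each other, 199 genes were higher and 111 lower after 4 injections than after 1, 304 were higher and 185 lower after 12 than after 1, and 30 were higher and 42 lower after 12 than after 4.

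Many genes passed 2-fold in the same direction in more than 1 comparison. The libraries with 4 and 12 injections shared 64 higher and 124 lower genes, where independent lists would share 3.34 and 12.1. Those with 1 and 4 injections shared 45 higher and 167 lower genes (3.51 and 31.6), and those with 1 and 12 shared 20 higher and 135 lower genes (2.07 and 29.9). In 100 simulations of unchanged libraries against the same untreated library, none was shared in any pair (0). The simulations hold counting error only, which does not reach 2-fold at 50 CPM, so this 0 says nothing of differences between animals. All comparisons use the same untreated library, which cannot be split, so part of the excess may come from it. Across the 3 comparisons 16 genes were higher and 110 lower in all, 124 were higher and 278 lower after 1 injection only, and 48 were higher and 14 lower after 4 and 12 injections but not after 1. These counts depend on the scaling: with TMM factors they were 27 and 64 in all, 299 and 128 after 1 injection only, and 53 and 19 after 4 and 12 but not 1. Without the activated untreated cluster described above they were 32 and 168, 171 and 294, and 60 and 24. The libraries with 4 and 12 injections shared 80 higher and 83 lower genes with TMM factors (5.67 and 6.17 if independent).

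After a single injection the genes with the highest ratios included Mt2, Ankrd1, Thbs1, Il11, Mt1, Tnfrsf12a, Hbegf, Ch25h, Atf3, Timp1 and Ccl7. Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568) had 3953 against 155 CPM in untreated cells, a ratio of 25.6 (24.6 to 26.6), and Mt1 had 5749 against 526 CPM. Thbs1 had 833 against 46.2 CPM and Timp1 793 against 90.6 CPM. Il11, with 117 against 0.634 CPM, had a ratio of 185 (103 to 370) that rests on 11 untreated UMIs. Without the activated untreated cluster the log2 ratios (10 CPM added) of Ankrd1, Ccl7, Timp1, Tnfrsf12a and Thbs1 were larger, at 5.39, 4.30, 4.24, 4.04 and 4.47 in place of 3.91, 2.93, 3.00, 3.29 and 3.91.

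The 12 lowest after a single injection were Zfp12, Inmt, Cadm1, Selenbp1, Angptl6, Acaa2, Igfbp3, Qpct, Vipr1, Islr, Gsta4 and Txnip, with log2 ratios from −4.35 to −2.81. Zfp12 (ENSMUSG00000029587, chromosome 5, 143235163 to 143248834) had 7.47 against 347 CPM, Angptl6 189 against 2161 CPM and Vipr1 82.5 against 678 CPM. Col1a1, the main fibrillar collagen gene, was not among the higher genes, with 490.4 CPM after 1 injection against 715 CPM in untreated cells and 373 CPM without the activated untreated cluster.

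After 4 injections the highest ratios were those of Igf1, Serpina3n, Nr4a1, Col15a1, Socs3, Plat, Gadd45b, Col1a1, Tagln, Thbs1, Col6a3 and Atf3. Igf1 (ENSMUSG00000020053, chromosome 10, 87858265 to 87937042) had 142 against 7.89 CPM, a ratio of 18.0 (15.2 to 21.5). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) had 4127 against 715 CPM, a ratio of 5.77 (5.66 to 5.88), and Col6a3 had 847 against 148 CPM. Without the activated untreated cluster the log2 ratio (10 CPM added) of Col1a1 was 3.43 in place of 2.51, that of Tagln 3.38 in place of 2.48, that of Plat 3.07 in place of 2.53 and that of Thbs1 3.04 in place of 2.47. Serpina3n had 55.7 against 0.461 CPM, a ratio of 121 (61.2 to 280.5). The lowest were Cadm1, Fcna, Inmt, Angptl6, Ecm1, Hhip, Ntm, Zfp12, Txnip, Pltp, Efemp1 and Vipr1, with log2 ratios from −3.80 to −2.33. Cadm1 (ENSMUSG00000032076, chromosome 9, 47530173 to 47857637) had 3.23 against 175 CPM, Fcna 200.5 against 2597 CPM and Ecm1 904 against 8456 CPM.

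After 12 injections the highest ratios were those of Igkc, Serpina3n, Igha, Igf1, Gpx3, Serpine2, Col15a1, Fhl2, Plat, Alcam, Svep1 and Gas6. Igf1 had 225 CPM, a ratio of 28.5 (24.0 to 34.0), Gpx3 519 against 39.4 CPM, Serpine2 366 against 25.1 CPM and Col15a1 119.7 against 2.65 CPM. Serpina3n had 147 CPM, a ratio of 319 (162 to 739.5) that rests on 8 untreated UMIs, and Svep1 had 56.7 against 0.634 CPM, a ratio of 89.4 (49.8 to 180). Igkc and Igha, the constant-region genes of immunoglobulins, had 179.9 and 134 CPM after 12 injections and no UMI in the untreated library, which makes them at least 1040.4-fold and 776-fold higher against a floor of 3 counts in that library. They had 4 and 9 UMIs after 4 injections, and whether their UMIs are free RNA was not tested. The lowest were Cadm1, Angptl6, Fcna, Hhip, Ntm, Inmt, Ecm1, Colec10, Tmem56, Vipr1, Egfem1 and H2-Q6, with log2 ratios from −3.86 to −2.42. Angptl6 had 142 CPM and Ntm 41.1 against 443 CPM.

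**Figure D4:**
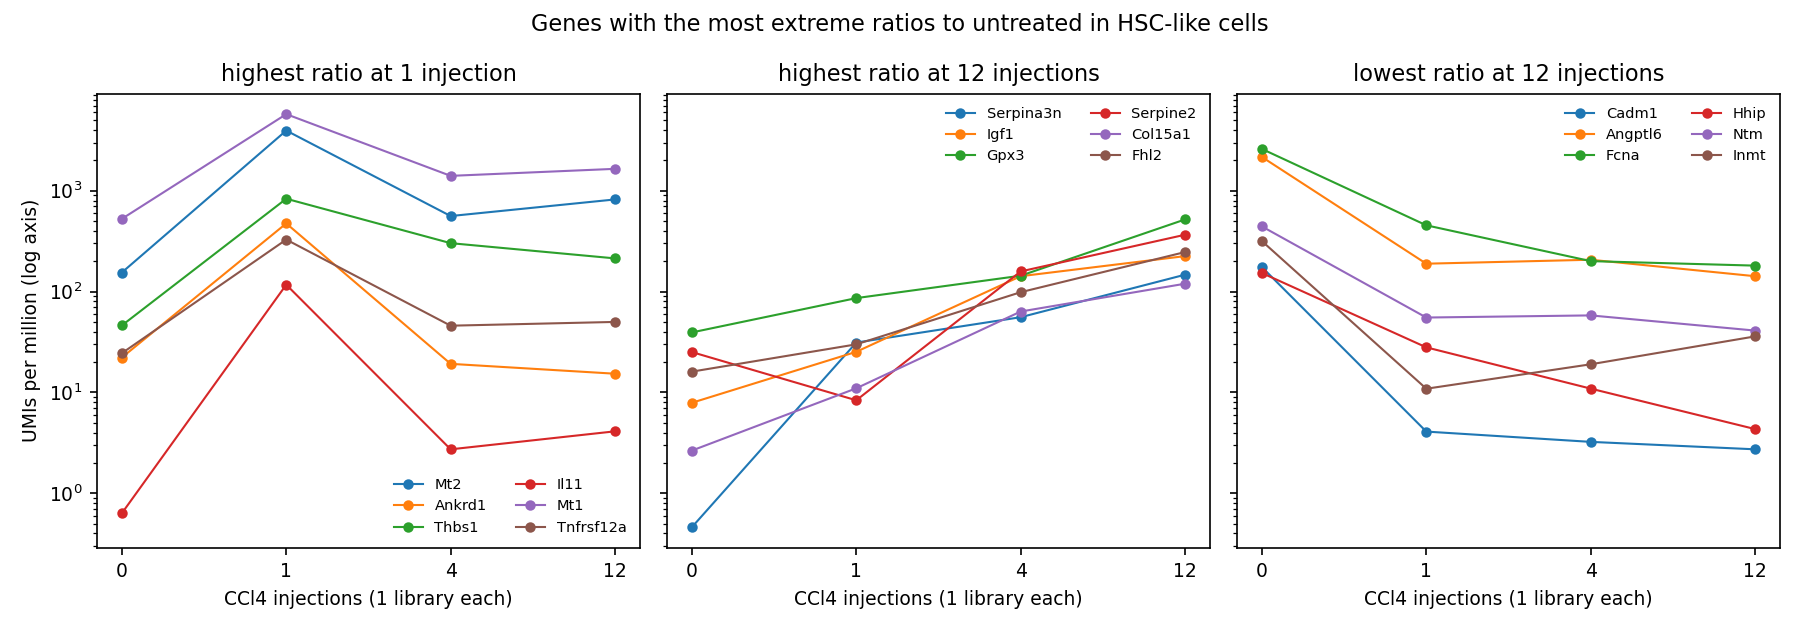
CPM (log axis) in HSC-like cells against the number of CCl4 injections for the 6 genes each with the highest ratios after 1 injection, the highest after 12 injections and the lowest after 12 injections, 1 line per gene, leaving out genes with no UMI in the untreated library. Mt2 goes from 155 to 3953 CPM at 1 injection and lies at 561 and 820.0 CPM at 4 and 12, while Igf1 lies at 142 and 225 CPM at 4 and 12.

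The 22 gene lists fixed beforehand were compared by the median log2 ratio of their members with at least 10 CPM in any sorted library. Only such members are called measured below. The percentile of that median among 10000 random lists matched on size and expression is given beside it. These percentiles describe the libraries and are no test across animals. Against untreated cells 6, 11 and 7 lists lay above the middle 95% of random lists after 1, 4 and 12 injections, and 4, 5 and 7 lay below it.

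The 18 quiescence genes of stellate cells had medians of −1.93, −1.24 and −1.30 after 1, 4 and 12 injections, each at percentile 0, with 15, 11 and 14 members at least 2-fold lower and none higher (0). Most of these genes, Reln, Ecm1 and Colec11 among them, are also markers that named the HSC-like cells. The list is therefore not independent of the choice of cells that entered the sums. Reln had 1160 CPM in untreated cells and 281, 448 and 445 CPM in the injured libraries. The 10 genes of retinoid and lipid droplet handling had medians of −1.28 (percentile 0), −0.19 (24.7) and −0.35 (1.70). The last lay inside the middle 95% under 4 of the alternatives, at percentile 5.30 as a mean over cells and 6.06 over all kept barcodes among them. Lrat (ENSMUSG00000028003, chromosome 3, 82892579 to 82903973) had 943 CPM in untreated cells and 368, 509 and 227 CPM after 1, 4 and 12 injections, whereas Rdh10 was higher after 1 injection (116 against 10.4 CPM) and Lpl after 12 (839 against 185 CPM).

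The 4 lists of matrix genes had higher medians after 4 and 12 injections than after 1. Set directly against the library with 1 injection, the medians after 4 and 12 were 1.22 and 1.33 for collagens, 0.72 and 0.95 for other matrix proteins, 0.56 and 0.64 for collagen processing, and 0.87 and 1.08 for proteases and inhibitors, each at percentile 99.7 or higher. Against untreated cells the 16 collagens had medians of −0.05 (percentile 61.5), 1.40 (100) and 1.18 (100), with 2, 11 and 11 members at least 2-fold higher. The median after 1 injection was 0.27 both with TMM factors and without the activated untreated cluster, and Col4a1 was higher even then (1119 against 427 CPM). The 20 other matrix proteins and crosslinkers had medians of −0.15 (38.7), 0.73 (100) and 1.00 (100). Thbs1 and Tnc (359 against 57.0 CPM, or 19.4 CPM without the activated untreated cluster) were their highest members after 1 injection. Eln was higher after 4 (139.9 against 24.1 CPM) and Ltbp2 after 12 (74.5 against 9.57 CPM). The 13 genes of collagen processing had medians of −0.23 (33.1), 0.21 (98.5) and 0.42 (99.98), and without the activated untreated cluster the median after 4 injections was at percentile 93.8, inside the middle 95%, as it was at 94.9 as a mean over cells. The 9 matrix proteases and inhibitors had medians of −0.33 (24.3), 0.65 (99.98) and 0.95 (100), with Timp1 high and Mmp2 low (12.5 against 113 CPM) after 1 injection.

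The 15 contractile and cytoskeletal genes had medians of 1.07 (100), 0.63 (99.97) and 0.49 (99.9), with 8, 3 and 3 members at least 2-fold higher after 1, 4 and 12 injections. Tagln had 738 CPM in untreated cells (389 CPM without the activated cluster) and 5277 CPM after 1 injection. Acta2 had 579 CPM in untreated cells (132 CPM without the activated cluster) and 1656, 1562 and 1568 CPM after 1, 4 and 12 injections. After 12 injections Acta2 depended on the removal of doublets, with 1059 CPM (log2 ratio 0.92) when none were removed and 910 CPM (0.70) at the automatic threshold, in place of a log2 ratio of 1.42. Without the activated cluster the median of the list was 1.10, 1.03 and 0.98. With doublets removed at the automatic threshold the list after 12 injections was at percentile 95.7, inside the middle 95%. The 18 immediate early and heat shock genes had medians of 1.12 (100), 0.70 (100) and −0.24 (5.08), and without the activated untreated cluster the last was −0.37 at percentile 0.40, and as a mean over cells −0.35 at percentile 0.77. Socs3 was high after 1 and 4 injections (308 and 245 against 33.9 CPM). These genes also respond to cell isolation, which was not separated from injury here.

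The 21 cell cycle genes depended on the untreated cluster of activated cells. Their medians were −0.61 (0.310), 0.57 (100) and −0.10 (61.5) after 1, 4 and 12 injections, and 0.09 (98.6), 1.33 (100) and 0.62 (100) without that cluster. The list was therefore highest after 4 injections in both calculations, whereas its side after 1 injection was reversed. As a mean over cells the medians were −0.14 (69.2), 0.96 (100) and 0.29 (100), and after 12 injections the list also lay above the middle 95% without doublet removal (0.19) and at the automatic threshold (0.13). Top2a had 30.9 CPM in untreated cells (12.8 CPM without the cluster) and 33.0, 125 and 37.6 CPM after 1, 4 and 12 injections.

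Of the inflammatory lists, only that of chemokines and cytokines had both positive and negative medians against untreated cells. The 15 chemokines and cytokines had medians of 1.29 (100), 0.16 (98.5) and −0.38 (0.285). The positions after 4 and 12 injections were inside the middle 95% without the activated untreated cluster, at percentiles 94.3 and 3.62, and after 12 injections as a mean over cells (3.42). Ccl2 (78.4 against 237 CPM) and Cxcl10 (7.97 against 43.9 CPM) were low after 12 injections. The 3 danger signal receptors measured, of 26 listed, had medians of 1.07 (99.7), 0.70 (99.3) and 0.61 (99.5). They do not stand for the whole list. Cd44 was higher after 1 injection (81.4 against 21.03 CPM). The 13 interferon response genes had medians of −0.42 (7.84), −0.83 (0) and −0.70 (0), and −0.60 at percentile 1.80 after 1 injection without the activated untreated cluster. Ifit3 had 221 CPM in untreated cells and 39.2 CPM after 4 injections. The 4 measured genes of class II antigen presentation had medians of −1.34, −1.41 and −1.57 (percentile at most 0.01), which rest on the activated untreated cluster: Cd74 had 50.3 CPM in untreated cells and 12.6 CPM without it, and too few members then reached the floor for a median. Over all kept barcodes, which include other cell types, the medians after 1 and 12 injections were −0.50 (10.5) and −0.17 (37.9), inside the middle 95%.

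Among signalling lists, the 10 growth factors and receptors had medians of 0.57 (99.9), 0.26 (99.6) and 0.25 (99.9). The 17 genes of the TGF-beta pathway had medians of 0.08 (95.7), 0.22 (99.8) and 0.04 (96.3). With TMM factors the first was at percentile 98.1, and the last passed the middle 95% under 5 of the alternatives, at 99.3 with the unnamed clusters. Itga8 (182 against 69.6 CPM) and Tgfb3 (40.6 against 9.22 CPM) were higher after 12 injections. The 10 ERK response genes had medians of 0.30 (98.8), −0.01 (75.0) and −0.21 (19.2), and the first was at percentile 94.3 without the activated untreated cluster. The 10 genes listed as YAP and TAZ targets had medians of −0.08 (70.9), −0.08 (59.5) and −0.22 (16.8). That list also holds the genes of YAP and TAZ themselves (Yap1 and Wwtr1) and Tead1. After 1 injection 3 members were at least 2-fold higher and none lower (0), with Ankrd1 21.4-fold higher. The 13 genes of ER folding and stress had medians of −0.38 (10.3), −0.50 (0.555) and −0.42 (0.450), and the 8 genes of the p53 response and senescence −0.23 (43.5), 0.00 (79.3) and −0.11 (51.5), where the log2 ratio of Cdkn1a was 1.16 after 1 injection and −1.22 after 12.

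The 5 purinergic receptors measured, of 19 listed, had medians of −0.49 (13.8), −0.71 (0.170) and −0.60 (0.560), with no member at least 2-fold different once 10 CPM were added. Besides P2ry14, P2rx4 had 54.6 CPM in untreated cells and 32.3, 25.8 and 32.6 CPM in the injured libraries, Adora2a 65.2 CPM and 43.5, 28.1 and 31.6 CPM, and P2ry1 13.9 CPM and 3.98, 9.47 and 9.61 CPM. P2ry2, the 5th member, went the other way after 1 injection, with 2.77 CPM in untreated cells and 13.9 CPM (log2 ratio 0.91 with 10 CPM added), and had 3.19 and 5.07 CPM after 4 and 12. The 6 genes of extracellular nucleotide metabolism had medians of −0.35 (26.4), −0.03 (70.2) and −0.02 (76.1), with Nt5e lower (69.6 against 14.2, 20.2 and 15.9 CPM) and Alpl higher after 1 injection (219.6 against 24.3 CPM). The 8 genes of UDP-sugar synthesis and transport had medians of −0.01 (86.8), 0.05 (89.4) and 0.00 (88.2), and none of them differed at least 2-fold (0).

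Marker lists of other cell types were read in the same HSC-like cells. Portal fibroblast markers (3 measured) had medians of −0.45, 1.28 and 2.44, vascular smooth muscle markers (4) 0.88, 1.08 and 1.11, and endothelial markers (3) −0.01, −0.63 and −0.55. The endothelial values depend on which cells count as HSC-like: they were −0.96, −0.99 and −0.94 (6 measured) without doublet removal, and 0.70, −0.77 and −0.71 (11 measured) with the unnamed clusters. Monocyte markers (3) had medians of −0.22, −0.32 and 0.34, or 0.24, 0.58 and 1.17 without the activated untreated cluster. Hepatocyte markers (5) had medians of 0.02, −0.06 and 1.19, the last at percentile 99.99, and the source of these transcripts was not tested. The other marker lists had fewer than 3 measured members. The erythroid list reached 4 at Leiden resolution 0.5, where after 12 injections all 4 were at least 2-fold higher (median 1.71), and 4 without a mitochondrial limit (1.80).

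**Figure D5:**
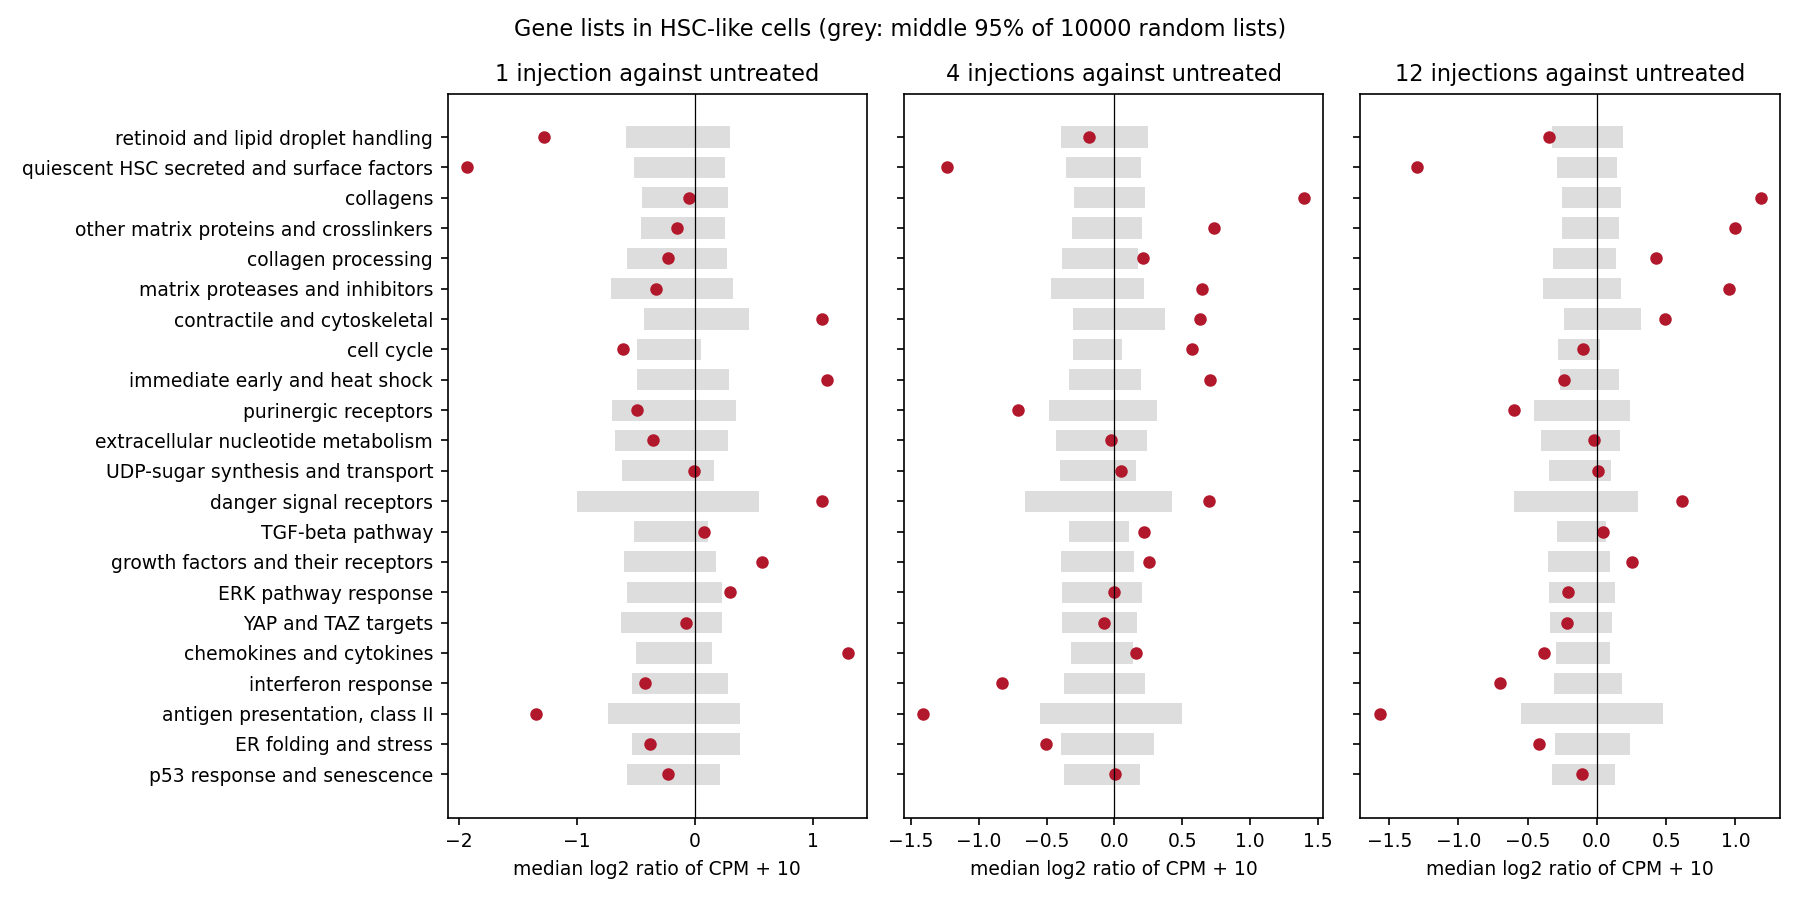
Median log2 ratio to untreated HSC-like cells of the 22 gene lists after 1, 4 and 12 injections (points, 1 panel each), with the middle 95% of 10000 random lists of the same size and expression in grey. The quiescence list lies below the grey range in every panel (−1.93, −1.24 and −1.30), and the collagens lie above it after 4 and 12 injections (1.40 and 1.18) but not after 1 (−0.05).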

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

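The marker genes Pecam1 and Dpep1 were picked for these clusters only after their values were seen, and no test of an explanation was run on them.

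A signal appeared in cells left out of the HSC-like sums and added back only in alternatives, namely clusters left unnamed because they carried markers of another class beside those of HSC. In the clusters with endothelial markers, Pecam1 stood at 192 CPM in the untreated library (142 to 254), 145.8 CPM after 1 injection (133 to 160) and 224 CPM after 4 injections (119 to 383). The HSC-like cells of the same libraries had 3.05, 1.71 and 1.75 CPM, and the limits that a count of 0 allows were 11.8, 0.994 and 51.7 CPM. Kdr stood at 682, 205 and 379 CPM and Stab2 at 368, 182 and 172 CPM in these clusters, beside 14138, 3814 and 4777 CPM of the stellate transcript Dcn. The median UMI count of the untreated cluster was 4130 against 4197 in its library, and those of the clusters after 1 injection were 5401.5 and 8223.5 against 7925. The cluster of 12 cells after 4 injections had a median of 3998 against 9534.5. Cells sorted for a stellate reporter that carry both sets of transcripts were not resolved further, and no biological explanation was tested.

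In the clusters with portal fibroblast or smooth muscle markers, Dpep1 stood at 124 CPM after 4 injections (106 to 144) and 328 CPM after 12 injections (313 to 344). The HSC-like cells had 5.45 and 46.6 CPM, and the limits that a count of 0 allows were 2.16 and 0.578 CPM. After 12 injections these clusters also had 547 CPM of Mfap4 against 68.5 CPM in HSC-like cells, 399.8 against 141 CPM of Eln and 41.1 against 6.54 CPM of Casq2, with less Lrat (70.4 against 227 CPM) and less P2ry14 (5.40 CPM, 3.59 to 7.80, against 36.5 CPM). Col1a1 stood at 6403 against 3893 CPM. No explanation was tested for these cells either.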

How the results depend on the processing

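The alternative without the activated cluster of the untreated library and the one with the unnamed clusters scoring highest as HSC were chosen only after the data were seen. Of the main results under 17 alternatives, 211 values stayed close to those reported and 48 moved. Among list medians 819 stayed, 53 moved and 1 was counted as reversed, although others changed sign too. Among named genes 567 stayed and 225 moved, and among class shares 113 stayed and 13 moved.

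The HSC-like share of the untreated library was 100% without doublet removal, at the automatic doublet threshold, and with the unnamed clusters. With the unnamed clusters it was 97.9%, 99.8% and 97.498% after 1, 4 and 12 injections. At Leiden resolution 2 it was 88.9% after 4 injections and 74.1% after 12. After 12 injections it was 79.1% without a mitochondrial limit, 61.6% without doublet removal, 67.1% at the automatic threshold and 84.7% at Leiden resolution 0.5. For the settings other than added clusters the cause was not tested.

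Thinning lowers shares of cells by its construction. At 1000 and 2000 UMIs the share of cells with P2ry14 was 9.31% and 16.6% in HSC-like and 16.9% and 35.2% in plasmacytoid dendritic-like cells of the whole liver. In the sorted libraries it was 7.30% and 14.7% untreated, 5.54% and 10.5% after 1 injection, 4.47% and 9.09% after 4, and 3.27% and 6.50% after 12.

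The log2 ratio of P2ry14 to untreated stayed negative under every listed alternative in which it was computed. Cells matched on quiescence transcripts, described below and not among those alternatives, gave 0.10 after 1 injection. After 1 injection the ratio over all HSC-like cells was −0.19 with TMM factors, and it was −0.71 without the activated cluster. After 4 injections it was −0.67 and −0.99. After 12 injections it was −0.89 and −1.22, −0.88 without doublet removal, −1.32 over all kept barcodes, −1.24 as a mean over cells and −1.30 with the unnamed clusters. The last sums include cells with little P2ry14, and for the other settings the cause was not tested.

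Counts of genes past 2-fold moved with the scaling and with the minimum CPM, which sets how many genes enter. After 1 injection they were 373 higher and 236 lower with TMM factors, 74 and 185 at a minimum of 200 CPM, and 260 higher with no minimum. After 4 injections they were 292 lower without the activated cluster, 50 higher and 96 lower at 200 CPM, and 205 higher with no minimum. After 12 injections they were 120 lower with TMM factors, 189 higher at a minimum of 20 CPM, 49 higher and 79 lower at 200 CPM, and 205 higher with no minimum. The single list median counted as reversed was the cell cycle list after 1 injection, at 0.094 without the activated cluster against −0.61 with it. That cluster holds 124 CPM of Top2a against 12.8 CPM in the other untreated cells. Other medians changed sign without being counted as reversed. With TMM factors after 1 injection collagens had 0.27 in place of −0.05, and collagen processing 0.11 in place of −0.23. With TMM factors higher genes also outnumbered lower ones in each comparison with untreated, whereas lower ones were more numerous without these factors.

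No paired analysis was possible because each group has 1 library. Depth limits shares of cells: at 1000 UMIs per cell the share with P2ry14 was at most 16.9% in any class of the whole liver.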

Other observations

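The tests of the name of the plasmacytoid dendritic-like cells, of cells matched on quiescence transcripts, and of the activated untreated cluster were chosen only after the result was seen.

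Genes that handle nucleotides and UDP-sugars were spread unevenly over the classes of the whole injured liver, by share of cells with a UMI as counted. Hepatocyte-like cells held Adk in 81.8%, Ugp2 in 65.9%, Ugdh in 52.6% (12 of 21 mesothelial-like cells, or 57.1%, did so too), Entpd5 in 43.2%, Slc35d1 in 37.0% and Gys2 in 34.7% of cells. Among the named classes Slc29a1 was highest in endothelial-like cells (71.3%, 453 CPM), with 64.8% and 157 CPM in HSC-like cells. HSC-like cells held Slc35d1 in 26.3% and Nt5e in 23.9%, where hepatocyte-like cells held Nt5e in 1.62%. Macrophage- or monocyte-like cells held Entpd1 in 44.6%, and Entpd2 was found in 42.9% of the 21 mesothelial-like and 39.1% of the 23 cholangiocyte-like cells. Among danger signal receptors, Il1r1 was found in 47.0% of HSC-like and 47.6% of mesothelial-like cells and Trem2 in 80.5% of macrophage- or monocyte-like cells.

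P2ry14 was higher in plasmacytoid dendritic-like than in HSC-like cells of the whole injured liver. Stellate RNA in their barcodes, as free RNA or doublets, was argued against: the Dcn and Colec11 UMIs per P2ry14 UMI reached at most 0.00337 of the ratio in HSC-like cells, with 32 Dcn UMIs against 22914. A wrong name was argued against by genes that played no part in the naming: 5 of 7 known from plasmacytoid dendritic cells were highest there of all classes beyond counting error, among them Irf8 (2450 against at most 396 CPM elsewhere) and Klk1 (582 against 27.4 CPM). Spib and Ptprs, with 305 and 139.9 CPM, were not beyond counting error. Expression of P2ry14 by these cells stays a hypothesis from 1 library, without untreated tissue to compare.

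P2ry14 was lower in HSC-like cells of the injured libraries. A few UMI-rich cells dominating the sums was argued against, since with every cell weighing the same the second lowest log2 ratio was −0.91 (range −1.24 to −0.62). Strongly induced genes taking up UMIs was argued against as the whole cause, since with TMM factors it was −0.67, and −0.89 after 12 injections, but it stays open after 1 injection, where the ratio was −0.19. A smaller share of cells rich in quiescence transcripts was tested first for 12 injections and then for the others. It is a candidate explanation after 1 injection, where cells matched on those transcripts gave 0.10 (−0.12 to 0.33, from 307 untreated cells). Without the activated untreated cluster the value was −0.07 (−0.39 to 0.25, from 198). The matching covered 88.9% of the HSC-like cells after 1 injection, and only 59.3% without that cluster. The injured cells so covered had 57.9 and 68.8 CPM of P2ry14, against 52.1 CPM in all HSC-like cells after 1 injection. Both values therefore describe part of that library. HSC-like cells with 2% to 4% of their UMIs from the quiescence list made up 75.3% in the untreated library and 0.34% after 1 injection. Matching cannot tell a loss of such cells from cells that each lowered these transcripts and P2ry14 together. After 4 and 12 injections the matched values of −0.36 (−0.60 to −0.12) and −0.65 (−0.89 to −0.40) leave it open how far that smaller share accounts for the difference. A direct effect of injury stays open too, untested with 1 library per group.

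The untreated library held 111 activated, UMI-rich cells. Doublets of untreated stellate cells were argued against by 21 of 2436 genes that lay at least 2-fold above every other untreated cluster beyond the counting intervals, among them Ldha (1505 against 491 CPM) and Mif (2708 against 712 CPM). Reads wrongly assigned from another sorted library were argued against by 0 barcodes shared with those libraries, where 1.57 would be by chance. Barcodes of the whole liver library were not compared, nor those of libraries outside the series. Carry-over of cells from another library and activation during isolation were not tested, and whether these cells come from the untreated liver could not be settled here.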
